A study of Mus musculus with 8 samples.

How the data were processed

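The samples were labelled as pro-B cells of mice, 4 labelled CD25 knockout and 4 labelled wild type. The replicate numbers 1 to 4 came from the sample titles. Per the labels' protocols, RNA was isolated with Trizol and libraries were made with a SMARTER mRNA-Seq kit. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. The sex-linked genes show that each group holds more than 1 animal.

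The values are raw counts of fragments per gene, deposited by the authors for 55487 genes. Per the file headers they were made with featureCounts 2.0.1 in paired mode over the exons of GENCODE M25, and every alignment of a multi-mapping fragment was counted. No strand setting is recorded there, so antisense and overlapping genes cannot be told apart, and genes with near-identical copies are uncertain. Per the submitters' processing notes, STAR 2.7.7a and GATK 4.1.9.0 were used with the mm10 build; the role of GATK is not given in the sources used here. The table also holds the summed exon length of each gene per the file headers, an annotation (unit: other) that entered no test. The table had 0 columns of other samples.

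Gene names, positions and GC content were taken from GENCODE M21 on GRCm38, the same build as mm10. Of the gene identifiers 55227 were found there and 260 stayed unnamed. Library totals ran from 43974040 to 57988770 counts. Every pair of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 29.5 over 12 pairs), so no library was counted as a copy of another.

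Everything that follows was computed from these counts. Genes were filtered with edgeR's filterByExpr, which left 18884, and scaled with TMM factors. They were tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, two-sided) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment over the genes tested at 0.05. The standard error of a log2 fold change was derived from the quasi-likelihood F value, and 95% intervals use its degrees of freedom. Given as "log2 fold change ± SE", values are libraries labelled knockout over wild type. CPM are TMM-scaled counts relative to library size, given as mean ± SD of 4 libraries, wild type first. The common biological coefficient of variation was 0.308 and the median SE was 0.16 on the log2 scale among genes with at least 5 CPM.

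Gene lists were written before the data were examined: 22 pathway or stage lists, 11 lists of markers of other cell types and the sex-linked genes as a sample check. Lists with at least 5 tested members (32) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. A list's score in a library is the mean deviation of its members' log2 CPM from their mean over the 8 libraries.

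The genes named followed a rule fixed before the data were examined. Il2ra came first. Next were up to 12 raised and 12 lowered genes past the adjusted p with at least 5 CPM and no overlap between groups, of which there were 0. Because fewer than 5 passed, the 5 genes with the smallest unadjusted p in each direction were named, leaving out predicted genes, pseudogenes and receptor gene segments. The members named in a list are those past the test or the 2 with the smallest unadjusted p. The sex-linked genes completed the set.

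Single values per library were compared with exact permutation tests, two-sided, for which 4 against 4 allows no p below 0.0286. The method was tested on simulated data drawn from the means of these libraries, with 200 of 18240 genes changed. It called 4.48% of 67 genes changed 1.5-fold, 65.7% of 67 changed 2-fold and 97.0% of 66 changed 4-fold, with 10 unchanged genes called. With no gene changed it called 0. In a separate draw camera with the preset correlation recovered 3 of 3 shifted lists and called 1 of 29 others. Genes were drawn independently of each other in every draw, while estimated correlations in the real lists reached 0.83. The draws therefore do not show what share of changed genes would be called in these data. Nor do they show how often the preset test calls unchanged lists in these data.

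The alternatives, fixed before the data were examined, were DESeq2 size factors, upper quartile factors, no or a stricter count filter, a replicate block, leaving out each replicate in turn, leaving out receptor segments, haemoglobin, mitochondrial and sex-linked genes, and a surrogate variable (sva 3.50.0). The others were DESeq2 1.42.0, limma-voom with quality weights, other thresholds, no robust estimation and a test against a 1.5-fold change. Chosen after seeing the data were a GC trend removed per library (loess of the log2 deviation on GC, span 0.5), sex as shown by Y-linked genes as a covariate, both of these with replicates left out, only libraries without Y-linked counts above 5 CPM, and wild type 4 thinned to the smallest total. A fit without labelled knockout 1 and 3, and comparisons of these libraries with the others, were run and then taken out, because the libraries had been picked by their scores. Sequence shared between Il2ra transcripts and other genes was searched with blastn 2.17.0 at 95% identity over 50 bases or more.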

Results

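RNA was sequenced from mouse cells labelled as pro-B cells, the early B lineage precursors of the bone marrow. The stage was taken from the labels. There were 8 libraries, 4 labelled as lacking CD25 and 4 labelled wild type. CD25 is the alpha chain of the interleukin-2 receptor and is encoded by Il2ra. Per gene the table held whole fragment counts, and each library summed to between 43974040 and 57988770 counts. The single comparison was of the libraries labelled CD25 knockout with the libraries labelled wild type. It was meant to ask which transcripts depend on the receptor chain at this stage.

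The targeted gene was read first, because it checks the labels. Il2ra (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193 on the plus strand of GRCm38) was not lower in the libraries labelled knockout by more than the spread between libraries. It had 193 ± 35.9 CPM (SD, n = 4) in wild type and 181 ± 43.1 CPM (SD, n = 4) in the libraries labelled knockout. The wild type libraries 1 to 4 held 200.2, 216.4, 215.6 and 140.4 CPM. The libraries labelled knockout 1 to 4 held 144.7, 168.3, 243.7 and 168.3 CPM. The ratio was 0.938 (log2 fold change -0.09 ± 0.19 SE, 95% interval from -0.51 to 0.32, adjusted p = 0.849, edgeR quasi-likelihood test). The counts are summed over all exons, so they do not show whether particular exons were missing. They therefore neither bear out nor refute the labels, and the group is called "labelled knockout" throughout; every direction given here rests on that label.

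**Figure D1:**
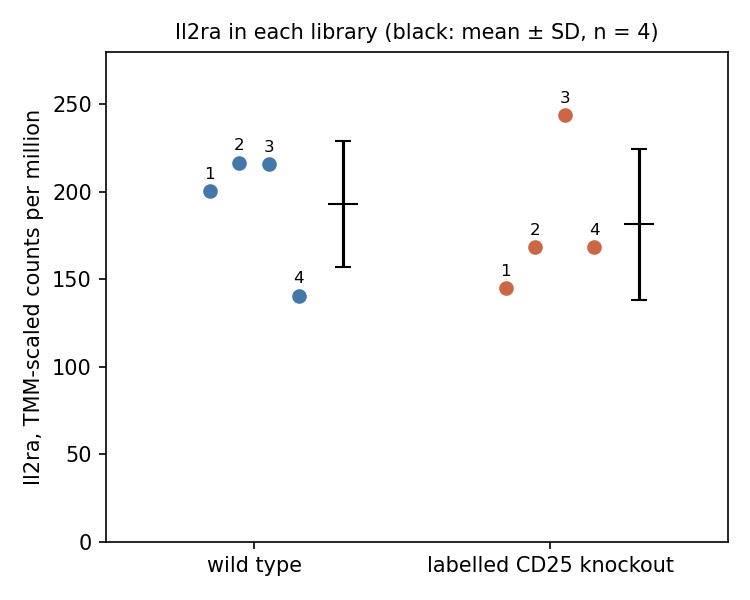
Il2ra in each library, in TMM-scaled CPM, with points for libraries (number: replicate) and black bars for the mean ± SD of 4 libraries. The libraries labelled knockout lie between 144.7 and 243.7 CPM and the wild type libraries between 140.4 and 216.4 CPM.

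Across 18884 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes different between the groups, and the smallest adjusted p was 0.391. DESeq2 and limma-voom also called 0. At an unadjusted p under 0.05 there were 2388 genes, 1045 higher and 1343 lower in the libraries labelled knockout. The threshold alone would give about 944 on average if no gene differed, with a wider spread where genes are correlated. Other splits of the same 8 libraries gave from 154 to 4107 such genes, and 4 of the 35 splits, the real one included, gave 2388 or more, so chance cannot be excluded for this count. It was 1195 without labelled knockout 1, 1205 without labelled knockout 3, 1208 without wild type 2 and 1395 without wild type 3. Of the 10462 genes with a mean of at least 5 CPM in a group, 82.4% had a 95% interval that lay within 2-fold either way. The count rested on wild type library 4. Without it 363 genes passed (358 higher, 5 lower in the libraries labelled knockout), all at an adjusted p of 0.0493 or more, and 0 passed in the same 7 libraries once the GC trend was removed (smallest adjusted p = 0.0584). The fold changes stayed about as large: the median log2 fold change of the genes called higher was 1.12 before and 0.96 after removal, and the genes at an unadjusted p under 0.05 went from 4277 to 4389. Without it and with the sex of the animals in the model, a term added after the data were seen, 3112 passed (2324 higher, 788 lower), and 3155 with the GC trend removed as well (1875 higher, 1280 lower). That term counts wild type 2, which held Xist as well as Y-linked counts, with the libraries carrying Y-linked counts above 5 CPM. No other wild type library is among these. Among the libraries labelled knockout the term parts 1 and 3 from 2 and 4, the same libraries that stand apart in several list scores (below), so it takes up that difference whatever its source.

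The genes with the smallest unadjusted p are given as values, since none of them passed. Dusp6, a phosphatase that dephosphorylates ERK kinases, had 131 ± 27.0 CPM in wild type and 262 ± 69.1 CPM in the libraries labelled knockout (SD, n = 4 each). Egln3, a prolyl hydroxylase of the hypoxia response, had 3.02 ± 0.582 and 6.63 ± 1.58 CPM, a log2 fold change of 1.13 ± 0.22 (SE). The kinase gene Sik1 had a log2 fold change of 0.73 ± 0.15, the mitochondrial valyl-tRNA synthetase gene Vars2 one of 0.88 ± 0.20, and the cholesterol exporter gene Abca1 one of 0.57 ± 0.12. On the lower side, Kntc1, a kinetochore component, had 40.6 ± 10.02 CPM in wild type and 20.6 ± 6.25 CPM in the libraries labelled knockout, a log2 fold change of -0.98 ± 0.25. Wdr76 had a log2 fold change of -0.52 ± 0.13, Ccdc82 one of -0.44 ± 0.10, Lxn one of -0.43 ± 0.11 and Pbdc1 one of -0.41 ± 0.10. All of these had an adjusted p of 0.391 in the edgeR test. Without wild type library 4, Egln3, Dusp6, Sik1 and Abca1 passed. Of the 56 tested genes within 5 Mb of Il2ra, 0 passed.

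The receptor's own pathway came first among the fixed gene lists. The list of the common gamma chain family held 14 genes, with Stat5a, Stat5b and Stat6 beside receptors and their kinases. Of these genes, 10 had higher and 4 lower values in the libraries labelled knockout, with a median log2 fold change of 0.26 (camera adjusted p = 0.081). None passed over all genes or adjusted over the list alone. Il4ra, the interleukin-4 receptor chain, had a log2 fold change of 0.40 ± 0.10 (SE). Il2rb, the beta chain of the interleukin-2 receptor, had 6.83 ± 2.79 and 3.12 ± 1.55 CPM. Natural killer cells also express Il2rb. Of the 16 STAT5 target genes, 13 were higher, with a median of 0.26 (camera adjusted p = 0.112) and 0 past the test adjusted over the list alone. Besides Il2rb the smallest unadjusted p among them belonged to Mcl1, a survival factor, with 90.2 ± 8.57 and 112 ± 10.2 CPM.

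By the camera test with its preset correlation, 14 of 32 lists passed, 3 higher and 11 lower in the libraries labelled knockout. With a correlation estimated per list 0 passed, and with fry 0 passed. The immediate early and heat shock genes had the highest median log2 fold change, 0.67, with 20 of 22 members higher (adjusted p = 4.5e-05 preset, adjusted p = 0.642 with an estimated correlation). Of these, Klf4 had a log2 fold change of 1.09 ± 0.35 and Klf2 one of 0.70 ± 0.23. The list's scores were 0.65 and 0.89 in labelled knockout 1 and 3, but -0.10 and 0.0080 in labelled knockout 2 and 4, below wild type 4 at 0.25. The B lineage transcription factors had a median of 0.30 with 17 of 21 higher (adjusted p = 0.00112 preset, adjusted p = 0.642 with an estimated correlation). Among them Ebf1, needed for B lineage commitment, had 575 ± 30.0 and 761 ± 144 CPM. Foxo1, which activates the Rag genes, had 81.7 ± 3.13 and 112 ± 24.4 CPM. Again labelled knockout 1 and 3 scored highest (0.28 and 0.32), with labelled knockout 2 and 4 at 0.0021 and 0.012, below wild type 4 at 0.054. The NF-kB targets had a median of 0.32 with 13 of 15 higher (adjusted p = 0.0262 preset, adjusted p = 0.642 with an estimated correlation). Their examples were Nfkbid at 0.95 ± 0.35 and Nfkbia at 0.82 ± 0.32 (log2 fold change ± SE). No member of these 3 lists passed over all genes or adjusted over the list alone.

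**Figure D2:**
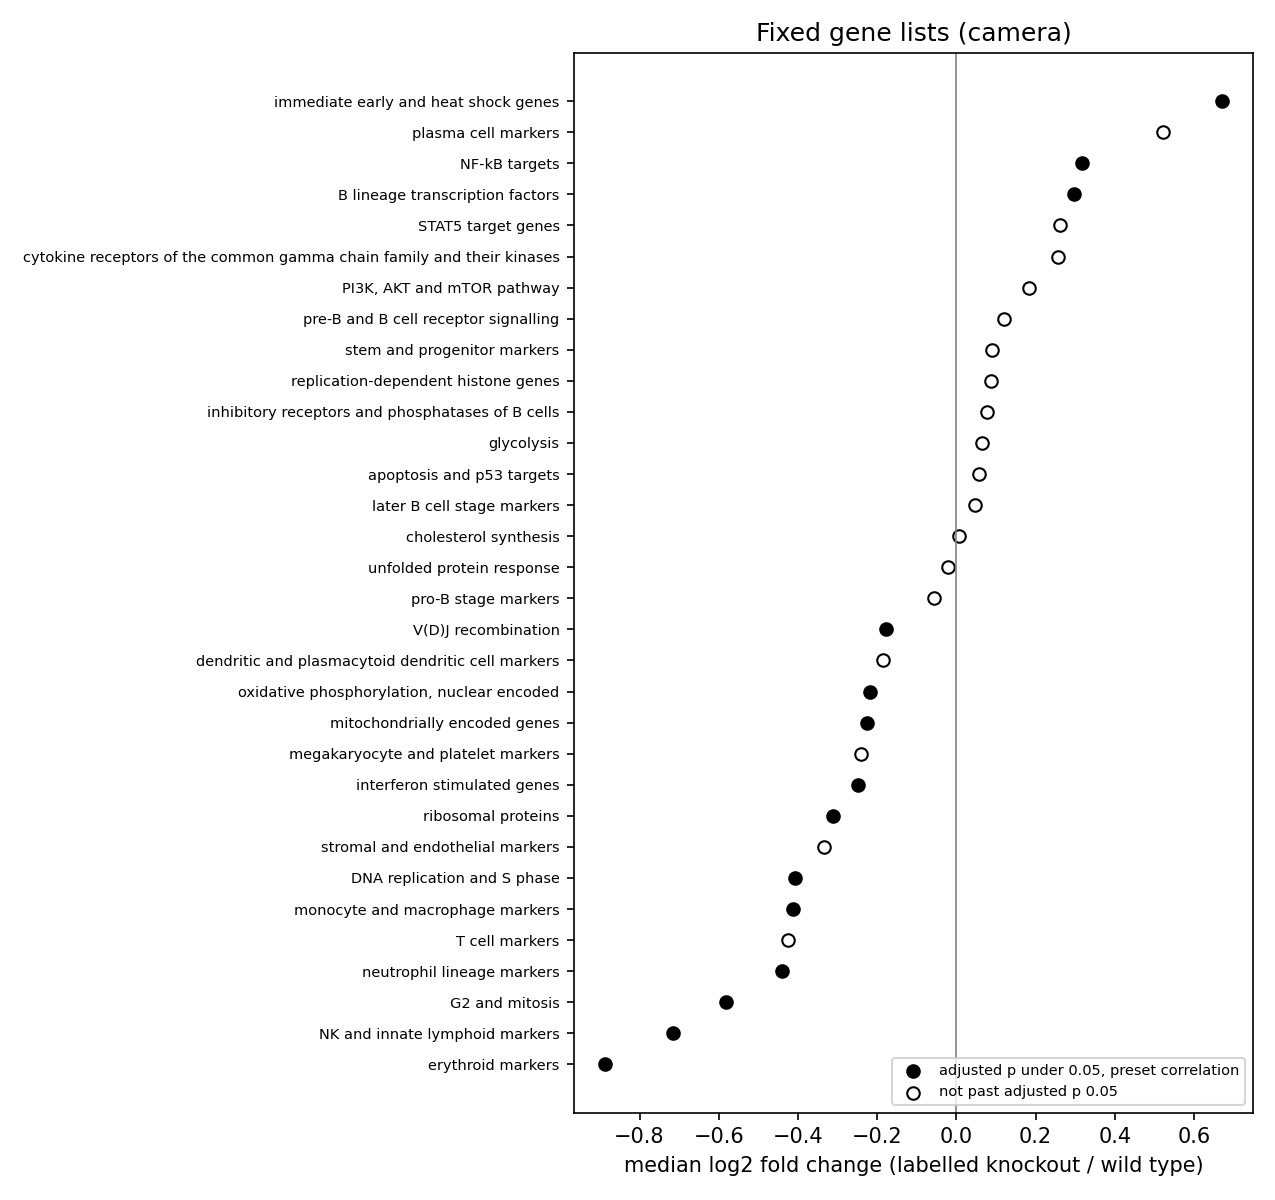
Median log2 fold change of the tested members of each fixed gene list, libraries labelled knockout over wild type. Filled points passed the camera test with preset correlation (14 of 32), open points did not, and none passed with an estimated correlation.

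Genes of cell division were lower as lists by the preset test alone. The G2 and mitosis genes had a median log2 fold change of -0.58 with 19 of 20 lower (adjusted p = 2.53e-06 preset, adjusted p = 0.642 with an estimated correlation). Bub1 and Bub1b, both of the spindle checkpoint, had log2 fold changes of -0.65 ± 0.21 and -0.61 ± 0.21. The DNA replication and S phase genes had a median of -0.41 with 17 of 20 lower (adjusted p = 3.07e-05 preset, adjusted p = 0.642 with an estimated correlation). Here 8 members passed adjusted over the list alone and 0 over all genes. Cdc6, a replication licensing factor, had 79.4 ± 10.5 and 52.3 ± 11.1 CPM, and Pole, the catalytic subunit of DNA polymerase epsilon, had 38.8 ± 6.85 and 23.5 ± 6.44 CPM. The libraries differed within the group: the G2 and mitosis score was -0.40 in labelled knockout 1 and -1.04 in labelled knockout 3, against 0.16 and 0.19 in labelled knockout 2 and 4. The wild type scores lay between 0.17 and 0.51.

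**Figure D3:**
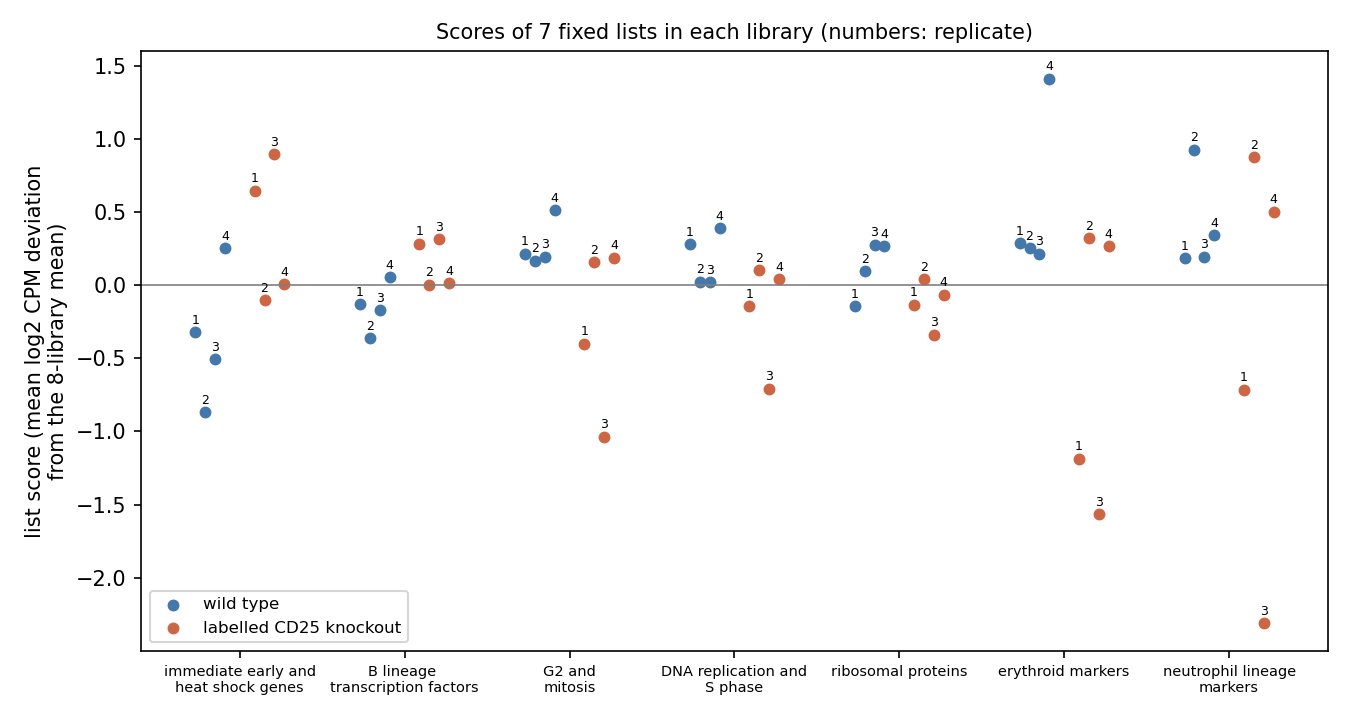
Scores of 7 fixed lists in each library (mean log2 CPM deviation of the members from their mean over the 8 libraries; numbers are replicates). In G2 and mitosis, labelled knockout 1 and 3 lie at -0.40 and -1.04, and the same libraries are lowest for the erythroid markers at -1.19 and -1.57.

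Ribosomal protein genes had a median log2 fold change of -0.31 with 22 of 24 lower (adjusted p = 2.53e-06 preset, adjusted p = 0.642 with an estimated correlation). Of them 19 passed adjusted over the list alone and 0 over all genes. Their score was -0.144 in wild type 1, below labelled knockout 1, 2 and 4 at -0.133, 0.042 and -0.064. Wild type 2 to 4 lay between 0.097 and 0.277, and labelled knockout 3 at -0.339 (exact permutation p = 0.143 for the groups). Rplp1 had 195 ± 28.7 and 136 ± 21.6 CPM and Rps18 had 389 ± 58.9 and 289 ± 39.6 CPM. Their counts are uncertain, because processed pseudogenes share their sequence and every alignment of a multi-mapping fragment was counted. All 13 mitochondrially encoded genes were lower, with a median of -0.23 (adjusted p = 1.83e-04 preset, adjusted p = 0.642 with an estimated correlation); mt-Co2 had 2122 ± 196 and 1663 ± 197 CPM and mt-Cytb had 2472 ± 146 and 2019 ± 239 CPM. The share of mitochondrial counts per library was 3.30 ± 0.133% and 2.81 ± 0.357%. The score of the 13 genes was 0.135 in labelled knockout 2, above wild type 1, 2 and 4 at 0.080, 0.090 and 0.058. Labelled knockout 1, 3 and 4 had -0.205, -0.256 and -0.154, and wild type 3 had 0.252 (exact permutation p = 0.114 for the groups). Nuclear genes of oxidative phosphorylation had a median of -0.22 with 17 of 21 lower (adjusted p = 0.0262 preset, adjusted p = 0.717 with an estimated correlation). Their examples were Ndufa4 at -0.42 ± 0.15 and Ndufb8 at -0.32 ± 0.12. Neither of the last 2 lists had a member past the test adjusted over the list alone.

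Genes of V(D)J recombination, which assembles the antigen receptor genes, had a median log2 fold change of -0.18 with 13 of 15 lower (adjusted p = 0.0262 preset, adjusted p = 0.642 with an estimated correlation). The 1 member past the test adjusted over the list alone, Polm, went the other way. This polymerase of end joining had 190 ± 58.4 CPM in wild type and 337 ± 53.9 CPM in the libraries labelled knockout. Hmgb1, a DNA-bending cofactor of the RAG recombinase, had 3477 ± 211 and 2579 ± 604 CPM. Interferon stimulated genes had a median of -0.25 with 21 of 25 lower (adjusted p = 0.0262 preset, adjusted p = 0.717 with an estimated correlation) and 0 past the test adjusted over the list alone. Stat2 at 0.51 ± 0.17 and Ifi44 at -1.07 ± 0.35 had values of opposite sign, and neither passed. Labelled knockout 4 had a score of 0.49, above every wild type library (up to 0.45), while labelled knockout 1 to 3 had -0.42, -0.38 and -0.31.

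Several lists of markers of cells other than B cells were lower by the preset test alone. Erythroid markers had a median log2 fold change of -0.89 with 11 of 13 lower (adjusted p = 1.84e-04 preset, adjusted p = 0.642 with an estimated correlation), and 5 members passed adjusted over the list alone. Alas2, the first enzyme of haem synthesis in red cells, had a log2 fold change of -1.59 ± 0.44 (SE). Hba-a1, an alpha globin gene whose near-identical copy Hba-a2 shares its reads, had 1173 ± 680 and 335 ± 216 CPM. Haemoglobin genes took 0.457 ± 0.251% of the counts in wild type and 0.130 ± 0.0890% in the libraries labelled knockout, with no overlap between the groups (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows; adjusted p = 0.229 over 8 library measures). Markers of natural killer and innate lymphoid cells had a median of -0.72 with 10 of 13 lower (adjusted p = 0.0262 preset, adjusted p = 0.717 with an estimated correlation). Nkg7 had 9.85 ± 2.18 and 4.53 ± 3.06 CPM, and Ncr1 had 4.23 ± 0.825 and 2.03 ± 1.22 CPM. Only labelled knockout 1 and 3 had low scores for this list (-0.48 and -1.45), while labelled knockout 2 and 4 had 0.39 and 0.43 (exact permutation p = 0.314 for the groups). Neutrophil markers had a median of -0.44 with 14 of 15 lower, and monocyte and macrophage markers one of -0.41 with 11 of 13 lower (adjusted p = 0.0262 preset and adjusted p = 0.717 with an estimated correlation for each). Elane had 8.53 ± 3.14 and 3.85 ± 3.70 CPM and Lcn2 had 26.4 ± 10.9 and 19.3 ± 9.45 CPM. F13a1, the 1 monocyte marker past the test adjusted over the list alone, had 16.2 ± 4.04 and 8.74 ± 2.20 CPM, and Csf1r had 2.40 ± 0.745 and 1.53 ± 0.483 CPM. The neutrophil and erythroid scores were lowest in labelled knockout 1 and 3, the libraries with the lowest G2 and mitosis scores. Erythroid scores of labelled knockout 2 and 4 were 0.32 and 0.27, near wild type 1 to 3 at 0.29, 0.25 and 0.21. Wild type 4 had 1.41 (exact permutation p = 0.257 for the groups). Neither the neutrophil nor the monocyte list passed without labelled knockout 1 or without labelled knockout 3.

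The other 18 lists did not pass the camera test. Pre-B and B cell receptor signalling had a median log2 fold change of 0.12 with 10 of 19 members higher (adjusted p = 0.375). Pik3ap1 had 666 ± 155 and 965 ± 180 CPM and Plcg2 had 215 ± 47.2 and 297 ± 32.3 CPM. Inhibitory receptors and phosphatases had a median of 0.08 (adjusted p = 0.221), and 2 members passed adjusted over the list alone. These were Dusp6 and the adaptor gene Dok3, with 828 ± 183 and 1207 ± 101 CPM. Pro-B stage markers had a median of -0.06 (adjusted p = 0.747), with Sox4 at 0.35 ± 0.13 and Erg at -0.63 ± 0.27. Later B cell stage markers had a median of 0.05 (adjusted p = 0.26), with Tnfrsf13b at 0.63 ± 0.24 and Cd37 at 0.32 ± 0.13. Glycolysis had a median of 0.06 (adjusted p = 0.789), with Pgk1 at -0.33 ± 0.10 and Ldha at -0.27 ± 0.09. The PI3K, AKT and mTOR pathway had a median of 0.18 with 14 of 17 higher (adjusted p = 0.0553). Replication-dependent histone genes had a median of 0.09 (adjusted p = 0.221), with Hist1h1c at 1.58 ± 0.42 and Hist1h1d at 0.89 ± 0.33. Histone genes are a family of similar copies, so their counts are uncertain. Their median ran from -0.11 to 1.15 with 1 library left out, the highest without wild type 4, whose score was 0.94 against -0.56, -1.06 and -0.11 in wild type 1 to 3. Apart from Dusp6 and Dok3, none of these lists had a member past the test adjusted over the list alone.

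In cholesterol synthesis the median was 0.01 and the mean -0.03, in apoptosis and p53 targets the median was 0.06 while camera pointed lower, and in the unfolded protein response the median was -0.02 and the mean 0.07 (adjusted p = 0.691, 0.955 and 0.747 by camera). These 3 lists had no common direction. T cell markers had a median of -0.42 (adjusted p = 0.112), plasma cell markers one of 0.52 (adjusted p = 0.636) and stromal and endothelial markers one of -0.34 (adjusted p = 0.375), again by camera. Megakaryocyte and platelet markers had a median of -0.24 (adjusted p = 0.43), dendritic cell markers one of -0.19 (adjusted p = 0.789) and stem and progenitor markers one of 0.09 (adjusted p = 0.535). Mast cell and basophil markers had 4 tested members, under the minimum of 5, and a median of -1.52. Of these lists none had a member past the test adjusted over the list alone. With upper quartile scaling the medians of the inhibitory receptor, later B cell stage, glycolysis, cholesterol, apoptosis and stem cell lists changed sign.

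The list calls depended on single libraries. The count of 14 became 7 without labelled knockout 1, 8 without labelled knockout 3 and 9 without wild type 2. The same 7 passed whichever library was left out: the immediate early, B lineage transcription factor, G2 and mitosis, replication, ribosomal protein, mitochondrially encoded and erythroid lists. With an estimated correlation each of these 7 had an adjusted p of 0.642 in all 8 libraries, and fry called none of them.

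The sex-linked genes showed that the groups mixed animals of both sexes. Xist, the transcript of the inactive X chromosome, lay at 482.5, 429.6 and 370.3 CPM in wild type 1, 3 and 4 and at 371.6 and 407.1 CPM in labelled knockout 1 and 3. In wild type 2 it was 60.0 CPM, and in labelled knockout 2 and 4 it was 0.348 and 1.12 CPM. The mean of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was 120.8 CPM in wild type 2, and 126.2 and 126.3 CPM in labelled knockout 2 and 4. It was 0.697 CPM in wild type 3, and at most 0.018 CPM in wild type 1 and 4 and labelled knockout 1 and 3. Wild type 2 thus held transcripts of both kinds. Wild type 3 held a trace of Y-linked counts beside Xist, the source of which was not tested. With 1 wild type library carrying Y-linked counts above 5 CPM, a test of the label within that sex would be weak, and it was not run. A fit of the other libraries, wild type 1, 3 and 4 against labelled knockout 1 and 3, was chosen after the data were seen. There 3105 of 19644 genes had an unadjusted p under 0.05 by edgeR. Its labelled knockout libraries are those that stand apart in several list scores.

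**Figure D4:**
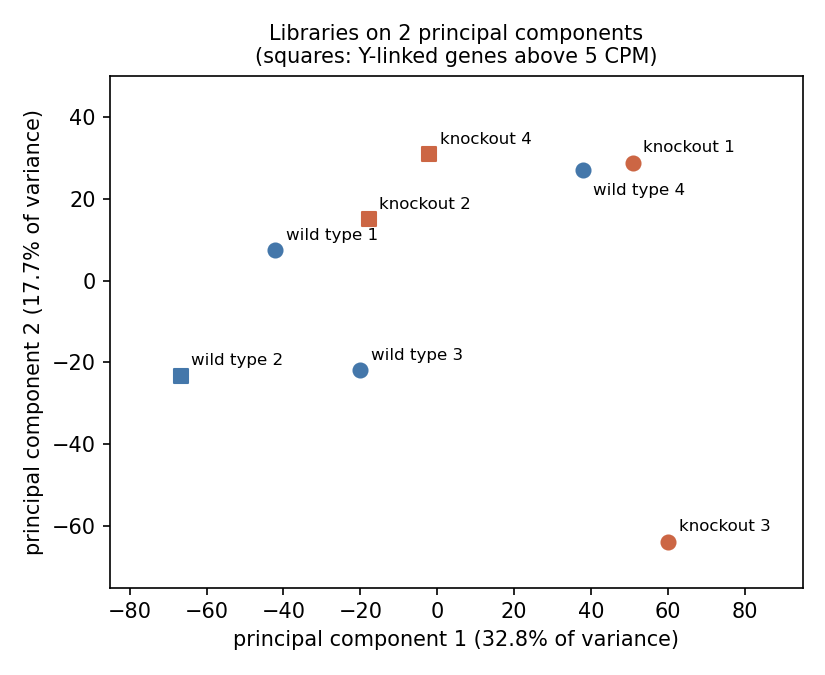
The 8 libraries on the first 2 principal components of log2 CPM, which hold 32.8% and 17.7% of the variance. Wild type 1, 2 and 3 lie at -42.1, -66.7 and -20.0 on the first component, while wild type 4 lies at 37.8, between labelled knockout 2 and 4 (-17.9 and -2.07) and labelled knockout 1 and 3 (50.9 and 60.1); squares mark libraries with Y-linked genes above 5 CPM.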

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

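Within each group of 4 libraries, the named genes, list scores and library measures were searched for a library far from the other 3. Of 236 groups examined 18 stood out, where chance gives about 11.8 (1 in 20).

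Wild type 2 stood apart in 10 of them. Its Y-linked genes were Ddx3y at 149.5 CPM, Uty at 48.2 CPM, Kdm5d at 73.0 CPM and Eif2s3y at 212.5 CPM, against at most 1.03 CPM in the other wild type libraries. Vars2 was 7.05 CPM there (others from 11.9), Pik3r1 92.4 CPM (others from 129.3) and Stat2 53.1 CPM (others from 81.7). Its unfolded protein response score was -0.44, its monocyte and macrophage score 0.97 and its stromal and endothelial score 0.69.

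Wild type 4 had the highest G2 and mitosis score at 0.51 (others up to 0.22), the highest erythroid score at 1.41 (others up to 0.29) and the highest haemoglobin share at 0.829% (others up to 0.383%). Wild type 3 had a score of 0.25 for the mitochondrially encoded genes, with the others up to 0.09.

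Among the libraries labelled knockout, number 1 had Abca1 at 62.3 CPM (others from 67.6), and number 3 had Pik3ap1 at 1235 CPM (others up to 888.4) and Srebf2 at 133.0 CPM (others up to 103.9). Number 4 had an interferon score of 0.49, with the others up to -0.31.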

How the results depend on the processing

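The fits with a GC correction, a sex term, only the libraries without Y-linked counts or a thinned wild type 4 were chosen after the data were seen; the others were planned. In edgeR, DESeq2 (2620 genes at an unadjusted p under 0.05) and limma-voom (3758 genes) the count of genes past adjusted p 0.05 was 0 in every fit of all 8 libraries, and the sex term came closest (smallest adjusted p = 0.0687 by edgeR, 4646 genes at an unadjusted p under 0.05). Leaving out 1 replicate gave 0 to 363 genes, above 0 only without wild type 4. With the sex term it gave 0 to 3112, with 108 without wild type 2 and 3112 without wild type 4, and 3155 with the GC trend removed as well. With the GC trend removed alone it gave 0 throughout. The log2 fold change of Il2ra ran from -0.27 to 0.0071 over left-out replicates, from -0.25 to 0.017 with the GC trend removed (0.015 without wild type 2, 0.017 without labelled knockout 1) and from -0.36 to 0.11 with the sex term (0.013 without labelled knockout 1). It was 0.11 in the libraries without Y-linked counts; it passed no test. The count of lists (14) was 0 with an estimated correlation and 0 with fry, which allow for correlated members. It ran from 7 to 16 over left-out replicates, from 6 to 12 with the GC trend removed (8 without wild type 4, 9 without wild type 2) and from 15 to 20 with the sex term (13 with both, without wild type 4). The replicate block gave 0 genes, 16 lists and -0.10 for Il2ra, with 3057 genes at an unadjusted p under 0.05 by edgeR, against 2388 without it. The deviations of same-numbered libraries correlated at 0.098, 0.321, 0.196 and -0.11 for numbers 1 to 4. Only numbers 2 and 3 correlated best with their own number, so pairing by number was neither shown nor excluded.

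Among list medians that changed sign, the cause was not tested. With upper quartile factors, which moved the median of all genes from 0.00 to -0.09, they were -0.026 (inhibitory receptors), -0.049 (later B cell stage), -0.021 (glycolysis), -0.094 (cholesterol), -0.045 (apoptosis) and -1.63e-06 (stem and progenitor). Unfolded protein response was 0.016 without a count filter, 0.013 with the sex term and 0.032 without Y-linked libraries. Apoptosis was -0.067 with the stricter filter, cholesterol -0.029 with the block and dendritic markers 0.10 with a surrogate variable. With the GC trend removed, glycolysis was -0.046, cholesterol -0.15 and apoptosis -0.00481. In the libraries without Y-linked counts, histones were -0.19 and stem and progenitor markers -0.092. Over left-out replicates the ranges were -0.064 to 0.057 (cholesterol), -0.11 to 1.15 (histones), -0.62 to 0.30 (dendritic), -0.65 to 0.18 (megakaryocyte), -0.11 to 0.067 (pro-B stage), -0.073 to 0.031 (unfolded protein response), -0.00788 to 0.15 (apoptosis) and -0.00702 to 0.14 (inhibitory receptors). Of the planned list results 436 stayed the same, 65 lost their call, 11 gained one and 27 changed sign. Of the planned gene results 1312 kept theirs and 12 came to pass, all without wild type 4.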

Other observations

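Antigen receptor segments were counted as a class. Of 291 segments tested by edgeR, 0 passed adjusted p 0.05 and 3 had an unadjusted p under 0.05, with a median log2 fold change of -0.03. The Ighv1 family, whose members lie mostly far from the joining segments, took 58.0 ± 0.818% of heavy chain V counts in wild type and 57.2 ± 0.744% in the libraries labelled knockout (SD, n = 4 each; exact permutation p = 0.171, adjusted p = 0.381 over 5 measures). The Ighv5 and Ighv2 families, nearer to the joining segments, took 12.2 ± 0.257% and 12.9 ± 0.531% (exact permutation p = 0.0857, adjusted p = 0.381), the opposite direction. Neither share passed. The lambda share of light chain constant region counts was 40.7 ± 2.42% and 40.1 ± 4.47% (exact permutation p = 0.8). That share is uncertain, because the lambda constant genes are near-identical and each alignment was counted. Ighm had 13207 ± 944 and 14000 ± 1025 CPM.

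Some stage markers were chosen after their values were seen and did not pass the edgeR test. The surrogate light chain genes Igll1 and Vpreb1 had log2 fold changes of -0.91 ± 0.40 and -0.86 ± 0.38 (SE), both with adjusted p = 0.393. Dntt, which adds bases at segment joints, had -0.91 ± 0.50 (adjusted p = 0.45). Il7r, the receptor chain that pro-B cells depend on, had 547 ± 21.1 and 539 ± 43.0 CPM, with a log2 fold change of -0.02 ± 0.08. Levels did not all go with the stage in the labels. Of the pro-B stage list, Kit had 1.76 ± 1.06 and 1.20 ± 0.488 CPM, but Igll1 163 ± 55.4 and 86.5 ± 51.3 CPM. Ms4a1 of the later stage list had 770 ± 87.4 and 657 ± 44.2 CPM. Ighd of that list had 161 ± 27.6 and 165 ± 15.1 CPM, but Cr2 5.04 ± 2.60 and 4.20 ± 0.354 CPM. Igkc, a light chain constant gene, had 3207 ± 525 and 3140 ± 261 CPM. The stage was not tested and rests on the labels.

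Of the tests below, those of GC content, of exchanged labels and of a remaining transcript were chosen after the result was seen. Thinning wild type 4, the sex term and counting that library as knockout were also chosen after the data were seen. With all 8 libraries the real split gave 0 genes, which all 35 splits into 4 and 4 reach whatever the data, so that count decides nothing; the highest other gave 1192. Chance cannot be excluded for the other counts. At an unadjusted p under 0.05, 4 of 35 splits gave as many as the real 2388 (highest other 4107), and for lists 8 of 35 gave as many as the real 14 (highest other 17). The split with 1192 genes set wild type 1, 2 and 3 and labelled knockout 2 against the rest, which is the real split with wild type 4 and labelled knockout 2 exchanged. It is the highest of the 35, and whether it reflects a structure among the samples beyond the labels was not tested.

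Without wild type 4, 363 genes passed, all at an adjusted p between 0.0493 and 0.05, and the sex term, added after this was seen, raised this to 3112 (2324 higher, 788 lower in the libraries labelled knockout, smallest adjusted p = 0.00155 by edgeR; 1875 higher and 1280 lower with the GC trend removed as well). Of the 35 splits of the 7 libraries only the real one (1) gave as many as 363 (highest other 1). Of 34 with the sex term only the real one (1) gave 3112 (highest other 818). That is the strongest result that so few splits allow. Wild type 4 was singled out because leaving it out gave calls, and the sex term was added later. The real split thus stood out among these splits, but chance is not excluded. Thinning wild type 4 gave 0 genes, so the size of its total alone does not account for the pattern. Other differences of that library were not addressed by thinning. Sex balance is argued against by the 3112 because more genes passed with the sex term. In the libraries labelled knockout that term also parts 1 and 3 from 2 and 4, which differ in several list scores, so the rise to 3112 is not tied to sex alone. The test of GC content first asked whether genes still passed in edgeR with the GC trend removed. Of these 0 did (smallest adjusted p = 0.0584), which fitted that explanation. After this was seen, the measure was changed to the median log2 fold change of the genes called higher. It was 1.12 before and 0.96 after removal (median SE of the called genes 0.22 and 0.19). The genes had been picked for large changes, and the highest of 5 GC classes deviated by -0.43 at most (wild type 2). This median could therefore hardly have fallen far. It shows that the trend was small beside these fold changes, not whether it carried the genes past the threshold. GC content stays open as an explanation of the calls. In the comparison of all 8 libraries, log2 fold change and GC content correlated at r = 0.309 across 9245 genes, which are not independent replicates, and the median ran from -0.09 in the lowest of 5 GC classes to 0.22 in the highest. An exchange of wild type 4 with labelled knockout 2 stays open: it gave the 1192 genes above in all 8 libraries, while counting labelled knockout 2 as wild type gave 0 genes in the 7 with the sex term. Counting wild type 4 as knockout gave 2240 genes in 8 libraries with the sex term. A wrong label of that library cannot be told apart from an unusual wild type sample, since Il2ra marks neither group. Wild type 4 had the fewest genes with a count, 25931, though its total was the largest, and labelled knockout 3 had 26141. The other libraries had from 29881 to 34965 such genes, and what this difference reflects was not tested. A difference between the labelled genotypes that wild type 4 does not share stays open as a hypothesis.

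In those 7 libraries with the sex term, 2324 of 19506 genes passed on the higher side and 788 on the lower. Among the lists, 13 of 22 immediate early and heat shock genes, 11 of 21 B lineage transcription factors, 9 of 18 histone genes, 7 of 15 NF-kB targets and 4 of 9 plasma cell markers passed on the higher side. So did 6 of 14 genes of the common gamma chain family list and 5 of 16 STAT5 targets. In each of these lists and among the histone genes 1 was lower. On the lower side 13 of 20 G2 and mitosis genes and 8 of 20 replication genes passed, with 1 replication gene higher. Fewer passed in other lists that kept their call whichever library was left out: 4 of 24 ribosomal protein genes lower and 2 higher, 3 of 13 mitochondrially encoded genes lower and 1 of 13 erythroid markers lower. Of the other markers of cells other than B cells, the medians were -1.24 for natural killer cells (2 of 13 passed), -1.07 for monocytes (2 of 13) and -0.81 for neutrophils (3 of 15). They were -1.57 for mast cells (1 of 5), -0.52 for T cells (1 of 14) and -0.54 for stromal cells (1 of 10). All of these members were lower. Dendritic (-0.75) and megakaryocyte markers (-0.81) had 0 passing, and stem and progenitor markers had a median of 0.36 with 1 of 7 higher. Oxidative phosphorylation had 3 of 21 higher and 5 lower. This fit was chosen after the data were seen.

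Il2ra counts as high in libraries labelled knockout as in wild type were weighed against 3 explanations. If the allele ended transcription, an exchange of labels between the groups would leave some libraries near 0, but the lowest had 76.2% of the median library. Reads of other genes are argued against, because 3.76% of the longest Il2ra transcript (166 of 4412 bases, from base 2250 to 2415) was shared with transcripts of 27 other genes. An allele that still gives a transcript from its remaining exons may account for the ratio of 0.938, and cannot be told apart from libraries with an intact gene, because the counts are not split by exon.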
